A study of Mus musculus with 10 samples.

How the data were processed

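RNA from isolated metanephric mesenchyme, the embryonic kidney tissue that surrounds the ureteric bud, was measured on 10 Affymetrix Mouse Genome 430 2.0 arrays, 5 of Wnt9b mutant and 5 of wild-type tissue. Per the labels' protocols, kidneys were dissected at E11.5, the mesenchyme was freed of the ureteric bud with trypsin and pancreatin, and 25 to 30 mesenchymes were pooled per array. About 1 ug of total RNA was extracted with Trizol, and biotin-labelled cRNA was made from it with an amplification kit. The protocol states that each array had its own RNA pool, so the spread between arrays includes that between pools. The sample labels give the controls as homozygous wild type, while the series' design text describes them as heterozygous. The sample labels were followed, and the groups are called mutant and wild type. Replicate numbers follow the order of the samples and only name the arrays.

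The values deposited by the authors are probe-set intensities on a linear scale, in 1 table for all arrays. The algorithm that summarised the probes into intensities is not given in the sources used here. In the values deposited, the mean intensity of each array after trimming 2% at each end was 250.0, so the arrays had been scaled to a common level before deposit. Values were used on the scale log2(signal + 1), called log2 signal below. Array medians lay between 5.99 and 6.30 on this scale, a range under the 0.5 set as the trigger for further normalization, so none was applied. A fold change on this scale understates the change of dim genes.

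The table held 45101 probe sets, of which 64 were controls and were left out of the tests. The platform annotation used here listed 35877 of them, 34945 with 1 gene symbol and 932 with several genes. The other 9160 probe sets were unnamed here. Of the probe sets with 1 symbol, 34741 were matched to RefSeq genes of GRCm38.p6 by gene identifier. Each gene was represented by its probe set with the highest mean over the 10 arrays, which gave 18193 genes, 9010 of them with more than 1 probe set. No genomic coordinates are printed because the array table names no build.

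Mutant and wild type were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with default settings, two-sided, and Benjamini-Hochberg adjustment over all genes. A gene was called at an adjusted p under 0.05. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 19 lists, with an estimated correlation and fry (statmod 1.5.0) as alternatives. fry tests whether a list's genes move one way, without comparing them with other genes. The 19 lists covered kidney compartments, Wnt targets, genes reported as Wnt9b-dependent in earlier work, other cell types that the dissection could hold, and signalling, cycle and stress groups. They held 228 entries, of which 212 were measured. The other 16 had no probe set with 1 gene symbol in the annotation and are not analysed here. Members were also counted after adjustment over the list alone. A list score is the mean log2 signal of its measured members in an array. Scores were compared with two-sided exact permutation tests over the 252 arrangements of the arrays, whose smallest p is 0.00794.

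The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule took Wnt9b, then the 15 largest rises and 15 largest falls among called genes whose groups did not overlap, skipping symbols that are only clone names. It then took up to 4 called members of each list, or the member with the smallest p if none was called. It gave 20 genes, because 1 gene was called. All other genes in the text were chosen after their values were seen. They are list members that passed over the list alone, further list members given as examples whether or not they passed, and genes called under another setting.

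The alternatives fixed beforehand were the mean of a gene's probe sets, each probe set on its own, leaving out the dimmest 40% of genes, quantile normalization, median centring, an intensity trend with robust moderation, array weights, a pseudocount of 16, a 2-fold minimum, an unmoderated test per gene, a block for arrays whose titles share wording, and leaving out each array in turn. After the data were seen, a block for the 18S control signal, each of the 2 sets of arrays it defines alone, a fit without the 2 arrays with the brightest hybridisation controls, and lists without the genes from earlier work were added. So were the splits of the arrays recounted without those genes, with an estimated correlation, and among splits balanced over the 18S sets. The rule for the list counts was first a share of splits under 5%, and after the shares were seen it was tightened for the 4 versions of the count. A fit with each array's ureteric bud score as a covariate was run and left all 5 lists of the closing observations lower. It was dropped because that score differed little between the groups, so adjusting for it could hardly change the list differences. The 13 lists described in the closing observations were also written after the table of all genes was opened.

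The calculation was tested on simulated data with the spread of these 18193 genes, with 50 genes changed at each of 4 sizes. For mutant minus wild type it recovered 2% of genes changed by 0.5 on the log2 scale, 44% at 1, 64% at 1.5 and 82% at 2. In the same simulation 1 unchanged gene was called. All 4 sizes were simulated together and 97 genes were called, which loosens the adjustment. The recovered shares therefore overstate what can be found where few genes are called, as in the real data. In a separate simulation without any effect no list was called. Its genes were drawn independently, whereas the estimated correlation within the real lists reached 0.589, so it does not check the list calls. Other splits of the real arrays, described at the end, called a median of 3 lists. Those splits cannot spread the 5 mutant arrays evenly over both sides, so they hold part of any genotype difference. The number of arrays limits the precision. No array was identical to another.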

Results

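Expression was measured in 10 pools of metanephric mesenchyme from E11.5 mouse kidneys, 5 from Wnt9b mutants and 5 from wild-type embryos, each on its own array. Wnt9b is a Wnt ligand of the ureteric bud, the epithelium that branches into the mesenchyme, and the comparison asks which mesenchymal transcripts differ when the ligand is missing. Pairs of arrays correlated at 0.915 to 0.954 over probe sets, with a median of 0.930 both within and between groups. The arrays fell into 2 sets by the 5' probe set of 18S ribosomal RNA, with signals of 1975 to 2587 on 4 arrays and 92.4 to 322 on 6. Each set held as many mutant as wild-type arrays, 2 of each and 3 of each. All 3 pairs of mutant and wild-type arrays whose titles share wording lay within a single set. The high-18S arrays were such pairs, wild-type replicate 2 with mutant replicate 5 and wild-type replicate 5 with mutant replicate 4. The blocks for title wording and for 18S are therefore not separate checks. Hybridisation controls were brightest on mutant replicate 2 and wild-type replicate 3, with mean log2 signals of 11.87 and 11.48 against 9.79 to 10.87 on the other 8 arrays.

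Btbd11, which encodes a protein with ankyrin repeats and a BTB domain, was the called gene. Its log2 signal fell from 9.14 ± 0.27 (SD, n = 5) in wild type to 7.56 ± 0.23 (SD, n = 5) in the mutant, 2.99-fold lower, with no overlap between the groups (difference -1.58, SE 0.16, limma adjusted p = 0.0427). A second probe set of Btbd11 gave a difference of -1.60 and another one of -0.35. The Btbd11 difference was -1.54 within the 4 arrays with high 18S signal and -1.61 within the other 6. Of 18193 genes, 999 had an unadjusted p under 0.05, where 909.65 would by chance, 620 higher and 379 lower in the mutant. That balance was not stable, with 490 higher and 452 lower without mutant replicate 3, and 467 higher and 626 lower in the high-18S arrays alone. Of the 100 splits of the arrays described at the end, 20 had at least 999 such genes, the real one included. The count of 999 therefore does not stand out from chance. The next smallest adjusted p was 0.283. Btbd11 was not called with the mean of its probe sets (-1.18, adjusted p = 0.293), with the block for shared title wording (adjusted p = 0.183) or with the 18S block (adjusted p = 0.103). It was called on leaving out wild-type replicate 5, and not on leaving out any other array, with adjusted p from 0.0766 without wild-type replicate 3 to 0.253 without wild-type replicate 2.

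Wnt9b itself did not differ detectably, with a log2 signal of 6.47 ± 0.14 (SD, n = 5) in wild type and 6.23 ± 0.54 (SD, n = 5) in the mutant (difference -0.24, SE 0.24, adjusted p = 0.996). Its signals were 78.2 to 99.7 in the wild-type arrays, 41.8 in mutant replicate 5 and 64.2 to 106 in the other mutant arrays. The difference was -0.76 within the high-18S arrays and +0.11 within the others. A dimmer second probe set of Wnt9b gave -0.78. By the protocol the ureteric bud, which makes the ligand, had been removed. Several bud genes were still measured, with wild-type means of 9.19 for Krt18 and 8.45 for Epcam, while Krt19, Rab25 and Esrp1 were dim. Where the Wnt9b probe sets lie relative to the deleted part is not given in the sources used here. The values therefore check nothing about the labels.

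**Figure D1:**
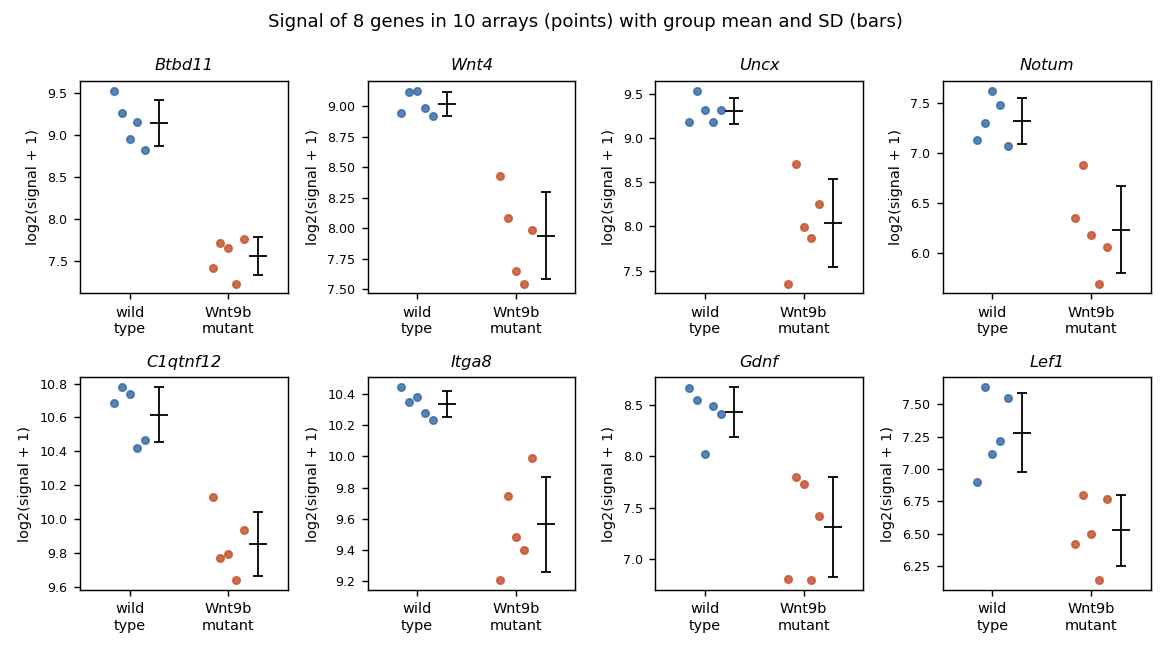
Log2(signal + 1) of 8 genes, 1 point per array, with the group mean and SD beside the points (n = 5 per group). In the main setting Btbd11 was the called gene, and the other 7 passed only after adjustment over their list alone. Under other settings Wnt4, Uncx, C1qtnf12 and Itga8 were also called. The wild-type points of Btbd11 lie around 9.14 and its mutant points around 7.56, without overlap.

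Genes of the nephron progenitors, the cap mesenchyme cells that give rise to nephrons, were lower in the mutant as a list. Of 16 measured members 14 were lower, with a median difference of -0.53, and 10 fell when adjusted over the list alone. None was called over all genes. Gdnf, the growth factor that draws out the ureteric bud, had a log2 signal of 8.43 ± 0.24 (SD, n = 5) in wild type and 7.31 ± 0.49 (SD, n = 5) in the mutant. Uncx differed by -1.28 (SE 0.22), Cited1 by -1.11 (SE 0.26), Itga8, an integrin of the mesenchyme, by -0.77 (SE 0.15), Eya1 by -0.73 (SE 0.20) and Six2, the regulator of progenitor renewal, by -0.66 (SE 0.22). Crym, Wt1, Meox1 and Spock2 were the other members that passed over the list alone, at -0.89, -0.52, -0.52 and -0.53. The members that did not pass were Meox2 at -0.54, Fgf20 at -0.48, Sall1 at -0.42, Osr1 at -0.04, Hoxa11 at +0.05 and Hoxd11 at +0.16. The fall was thus not uniform over the list. Camera put the list lower (adjusted p = 4.26e-14). The correlation between the list's genes was estimated at 0.458, far above the preset 0.01, and with that estimate the call was lost (adjusted p = 0.0647). The list score was 9.15 ± 0.08 (SD, n = 5) in wild type and 8.57 ± 0.34 in the mutant, without overlap (exact permutation p = 0.00794, the smallest possible, 0.0503 after adjustment over the lists). The score difference was -0.52 within the high-18S arrays and -0.63 within the others. Within these sets Cited1 differed by -0.43 and -1.57, and Wt1 by -0.31 and -0.67.

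Genes of nephron induction, which mark the mesenchyme's first steps towards epithelium, were also lower as a list. Of 14 measured members 10 were lower (median -0.43), and 5 fell when adjusted over the list alone. Wnt4, the Wnt ligand that drives the conversion to epithelium, went from 9.02 ± 0.10 (SD, n = 5) to 7.94 ± 0.36, a difference of -1.08 (SE 0.17). C1qtnf12 differed by -0.76 (SE 0.13), the transcription factor Pax8 by -0.97 (SE 0.28) and the cadherin Cdh4 by -0.73 (SE 0.24). Fgf8 differed by -2.46 (SE 0.50) at signals of 3.6 to 78.8, low enough that the size depends on the pseudocount, and gave -1.32 with a pseudocount of 16. Lhx1, another dim member, was at +0.30 (SE 0.64), with -1.40 within the high-18S arrays and +1.43 within the others. Camera gave an adjusted p of 6.29e-07, and 0.00738 with an estimated correlation. Without the 4 members that are also on the list from earlier work, Wnt4, Fgf8, Pax8 and C1qtnf12, the call was lost (adjusted p = 0.0680). The exact permutation p of the list score was 0.00794, and 0.0503 after adjustment over the lists. The score difference was -0.64 within the high-18S arrays and -0.42 within the others.

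All 9 genes on the list of Wnt9b-dependent genes from earlier work were lower in the mutant, and all 9 fell when adjusted over the list alone (median -1.08). Besides the genes already given, Pla2g7 differed by -1.38 (SE 0.30), Tafa5 by -1.01 (SE 0.37) and Amph by -0.81 (SE 0.19). Pla2g7 was at -0.88 within the high-18S arrays and -1.71 within the others. Camera gave an adjusted p of 4.37e-21, and 0.000407 with an estimated correlation. The list score had an exact permutation p of 0.00794, adjusted 0.0503. The earlier work may rest in part on these arrays, so the list is not independent evidence of its direction.

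Feedback and target genes of canonical Wnt signalling were lower as a list, with 10 of 13 members lower (median -0.29), 4 of which fell when adjusted over the list alone. Notum, a secreted Wnt inhibitor, went from 7.32 ± 0.23 (SD, n = 5) to 6.23 ± 0.43 (difference -1.08, SE 0.21). Lef1, a transcription factor of the pathway, differed by -0.76 (SE 0.18), Myc by -0.39 (SE 0.12) and the dim gene Sp5 by -1.76 (SE 0.38), or -0.78 with a pseudocount of 16. Axin2, a widely used readout of the pathway, differed by -0.29 (SE 0.22) and did not pass, and ran from -0.18 without mutant replicate 4 to -0.45 without mutant replicate 2. Wif1 and Rnf43, both dim, did not pass either, at +1.00 and +1.17, or +0.49 and +0.52 with a pseudocount of 16. Lef1 was at -1.14 within the high-18S arrays and -0.50 within the others. Camera gave an adjusted p of 0.000111, and 0.0140 with an estimated correlation. The list score did not pass after adjustment over the lists (exact permutation p = 0.0238, adjusted 0.0905). The score difference was -0.35 within the high-18S arrays and -0.17 within the others.

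All 8 feedback genes of FGF and receptor tyrosine kinase signalling were lower (median -0.40), though none passed over the list alone. Etv5, a transcription factor induced by this signalling, differed by -0.75 (SE 0.23), Spry1, an inhibitor of it, by -0.49 (SE 0.18), and Etv4 by -1.44 (SE 0.67). Etv4 was at -0.78 without mutant replicate 1, and its second probe set was at +0.03. Camera put the list lower (adjusted p = 1.66e-06, and 0.0478 with an estimated correlation). The list score did not pass after adjustment (exact permutation p = 0.0238, adjusted 0.0905). The score difference was -0.38 within the high-18S arrays and -0.61 within the others.

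**Figure D2:**
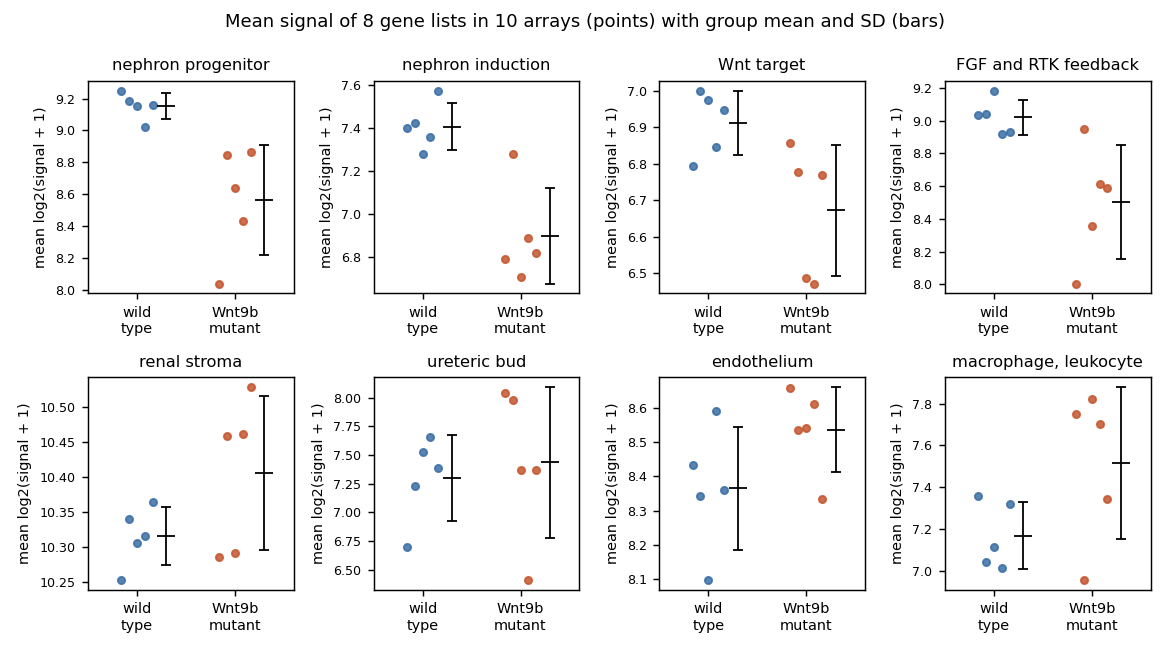
List scores (mean log2(signal + 1) of the list's measured genes), 1 point per array, with the group mean and SD beside the points (n = 5 per group). For nephron progenitor genes the wild-type mean of 9.15 lies above the mutant mean of 8.57 without overlap, while the renal stroma, ureteric bud, endothelium and leukocyte scores overlap between groups.

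Among markers of other cell types, those of macrophages and leukocytes were higher in the mutant in 10 of 10 members (median +0.35), with none passing over the list alone. C1qa, a complement gene of macrophages, differed by +0.73 (SE 0.27). The list was called higher (adjusted p = 0.00150), but not with an estimated correlation (adjusted p = 0.330) nor within the low-18S arrays (adjusted p = 0.0601). All 12 endothelial genes were higher (median +0.14), none passing over the list alone, with the cadherin Cdh5 at +0.26 (SE 0.14), or +0.16 without mutant replicate 4. That call (adjusted p = 0.0233) was lost with an estimated correlation (adjusted p = 0.330). It was also lost on leaving out mutant replicate 1 (0.0864) or 4 (0.106), or wild-type replicate 2 (0.0574) or 3 (0.163). Neuron and neural crest genes were higher in 5 of 7 members, and Stmn2 and Foxd3 rose when adjusted over the list alone, by 0.67 (SE 0.19) and 0.99 (SE 0.32), the dim Foxd3 by 0.64 with a pseudocount of 16. That list's call (adjusted p = 0.0318) was lost with an estimated correlation (adjusted p = 0.330). Leaving out mutant replicate 1 (0.192) or 4 (0.0539), or wild-type replicate 1 (0.0773), 3 (0.106) or 5 (0.0740), also ended it. Renal stroma was not called (8 of 13 members higher, adjusted p = 0.210), with Pdgfra at +0.36 (SE 0.11) on its brightest probe set and +0.01 and +0.17 on the others. Neither was ureteric bud epithelium (9 of 14 higher, adjusted p = 0.296), with Sox9 at +0.44 (+0.68 without mutant replicate 3). The ureteric bud list was called higher within the low-18S arrays (adjusted p = 0.00272) and without mutant replicate 4 (0.00293), and was lower, uncalled, within the high-18S arrays (0.201). Erythroid genes were higher in 7 of 9 members and not called (adjusted p = 0.185), with Gata1 at +0.56. They were called higher without wild-type replicate 3 (0.00983) or mutant replicate 5 (0.0410).

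Cell cycle genes were lower in 14 of 15 members by small amounts (median -0.12), none passing over the list alone, with Mcm2, a DNA replication factor, at -0.40 (SE 0.16), or -0.24 with the mean of its probe sets. The call (adjusted p = 0.00495) was lost with an estimated correlation (adjusted p = 0.330), within the low-18S arrays (0.130) and without wild-type replicate 3 (0.143). The Notch pathway list was called lower (adjusted p = 0.0496) although its median was +0.01, its mean -0.08, and 6 of its 11 members were higher. Notch2 differed by -0.45 (SE 0.14) and Jag1, a Notch ligand, by -0.48, or by -0.28 and -0.30 with the mean of their probe sets. The Notch call was lost with an estimated correlation (adjusted p = 0.330). It was lost too without mutant replicate 2 (0.176), 3 (0.0787) or 5 (0.140), or wild-type replicate 1 (0.143), 2 (0.271) or 4 (0.0695).

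No call was made for the lists of p53 targets (adjusted p = 0.738), hypoxia and glycolysis (0.134), immediate early and stress genes (0.969), BMP and TGF-beta response (0.335), planar cell polarity (0.360) or sex-linked genes (0.969). The members with the smallest p were Trp53inp1 at +0.27, Hk2 at -0.62 (SE 0.16), Zfp36 at +0.24, Bmp4 at +0.38, Prickle1 at +0.38 and Xist at +0.14. Without mutant replicate 2 Trp53inp1 was at +0.40 and Zfp36 at +0.12, without mutant replicate 3 Zfp36 was at +0.43, and without wild-type replicate 3 Prickle1 was at +0.24. Within the high-18S arrays and within the others, Zfp36 was at +0.59 and +0.01 and Trp53inp1 at +0.44 and +0.15. Without the 2 arrays with the brightest hybridisation controls they were at +0.06 and +0.44. With the mean of its probe sets Prickle1 was at +0.23. Xist turned to -0.01 without mutant replicate 2. Hk2, a glycolytic hexokinase, fell when adjusted over the list alone. Hypoxia and glycolysis was called lower without mutant replicate 2 (0.0239) or wild-type replicate 4 (0.0329), and immediate early and stress genes were called higher without mutant replicate 3 (0.0424) and within the high-18S arrays (0.00429). In all, 10 of 19 lists were called, 7 lower and 3 higher. The 4 calls that held with an estimated correlation were nephron induction, canonical Wnt, FGF feedback and the list from earlier work, and fry called those and the progenitor list.

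**Figure D3:**
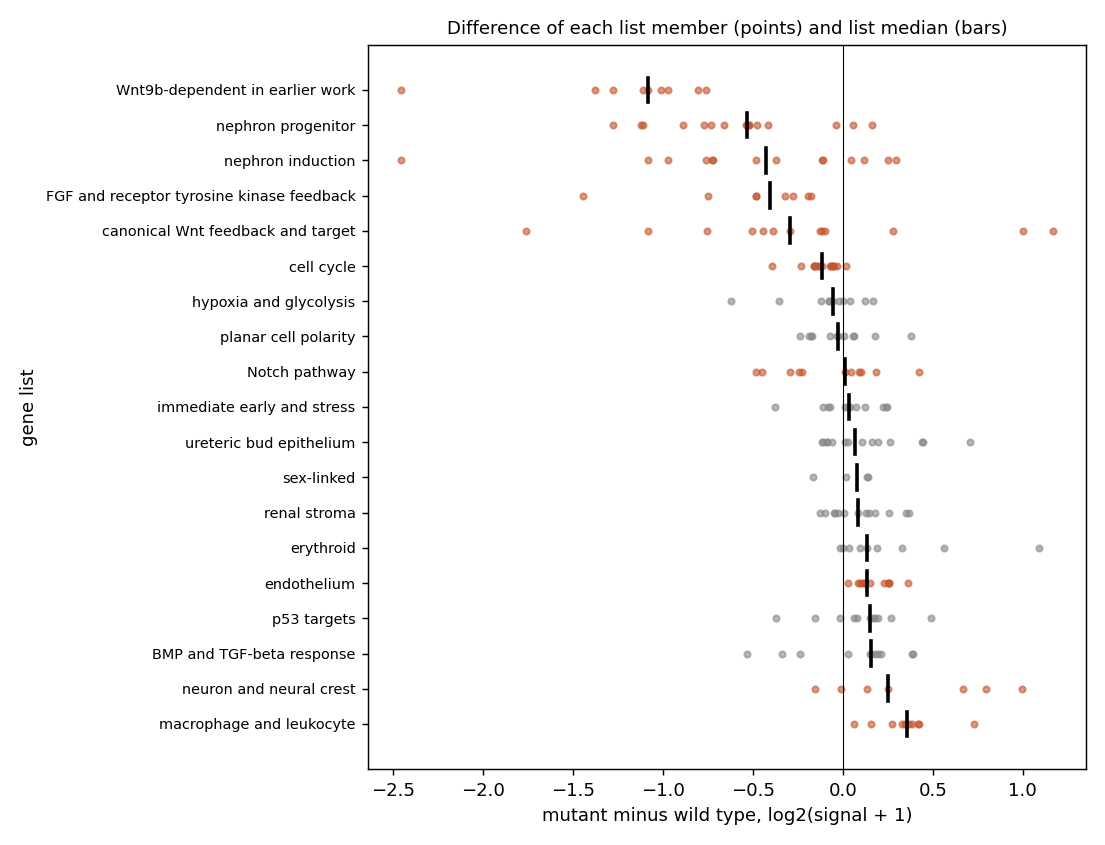
Difference between mutant and wild type for each measured member of the 19 lists (points, log2(signal + 1) scale) and the list median (bars). Lists called by camera are in red and the others in grey. Medians run from -1.08 for the genes from earlier work to +0.35 for macrophage and leukocyte genes.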

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

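Within each group of 5 arrays, the array farthest from the rest was compared with the group's range for the genes named in the text, the list scores and the array controls, 154 groups of values in all. Collagen genes other than Col9a1 were not among them. Chance alone marks about 1 group in 20, or 7.7 here, and 6 were marked. No explanation was tested for them.

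Sox9 had a log2 signal of 7.57 in mutant replicate 3, against 8.66 to 8.89 in the other mutant arrays. Myc was at 8.90 in wild-type replicate 4, against 9.20 to 9.27 in the other wild-type arrays. Wild-type replicate 5 was highest among wild-type arrays for 2 dim genes, Cep295nl at 5.22 against at most 3.97 and Rnf43 at 4.33 against at most 2.46. Mutant replicate 2, which also had the brightest hybridisation controls, had the highest score of the p53 target list among mutant arrays, at 7.71 against 7.12 to 7.20. The same array had the highest score of the hypoxia and glycolysis list, at 9.17 against 8.86 to 8.94.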

How the results depend on the processing

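The 18S settings, the fit without 2 arrays and the lists without genes from earlier work were chosen after seeing the data. The progenitor, induction, Wnt target, FGF feedback and earlier-work lists stayed lower with adjusted p under 0.05 in the camera and fry settings run on lists, except that the progenitor list had 0.0647 with an estimated correlation and the induction list 0.0680 without the genes from earlier work. With both changes together the adjusted p was 0.157 for progenitor, 0.311 for induction, 0.0906 for FGF feedback and 0.0398 for Wnt targets. Exact permutation of the list scores passed for none of the 5 after adjustment (0.0503 to 0.0905). The progenitor, induction and earlier-work lists already had the smallest possible p, 0.00794. Their adjusted p of 0.0503 thus reflects the number of arrays and lists, and does not count against them. Lists were not run with the unmoderated test, the 2-fold minimum or single probe sets. No list changed its call or direction under quantile normalization, median centring, trend and robust moderation, a pseudocount of 16, the title-wording block or the 18S group block. The median gene difference stayed between -0.01 and +0.05 in all settings. Dim genes such as Fgf8 and Sp5 have sizes that depend on the pseudocount. Where a call ended or reversed, the cause was not tested, except that fits on fewer arrays have less power by construction.

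Called genes numbered 1. They were 0 with the mean of a gene's probe sets, the title-wording block, the 18S group block, the high 18S arrays alone, the low 18S arrays alone, the fit without the 2 arrays with the brightest hybridisation controls, and the unmoderated test per gene, and 2 with every probe set on its own. With the low 40% of genes left out there were 6, namely Btbd11, Cxcr4, Ppp1r16b, Rasef, Uncx and Wnt4, all lower. With trend and robust moderation there were 10, those 6 with C1qtnf12, H2-Ab1 and Itga8 lower and Col9a1 higher. Leaving out each array in turn gave 0 to 2, the 2 being Btbd11 and Cep295nl without wild-type replicate 5. Quantile normalization, median centring, array weights, a pseudocount of 16 and a 2-fold minimum each kept the count at 1.

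With an estimated correlation the adjusted p was 0.3297 for endothelium, macrophage and leukocyte, neuron and neural crest, cell cycle and Notch. With fry it was 0.233 for endothelium, macrophage and leukocyte, and neuron and neural crest, and 0.3805 for cell cycle and Notch. With the mean of probe sets Notch was at 0.1883, the sex-linked list turned lower (0.8098) and Xist turned to -0.2265, Lhx1 to -0.1937 and Cd109 to -1.122. With the low 40% left out the neuron list was at 0.07078. With array weights endothelium was at 0.05685 and the neuron list at 0.05533, and Lhx1 turned to -0.05697.

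In the high 18S arrays alone the adjusted p was 0.1304 for endothelium, 0.2285 for neuron, 0.1338 for Notch and 0.004294 for immediate early genes, and the ureteric bud list turned lower (0.2006) and Lhx1 to -1.402. In the low 18S arrays alone it was 0.002723 for ureteric bud, 0.07002 for endothelium, 0.06013 for both leukocyte and neuron lists, 0.1301 for cell cycle and 0.1793 for Notch. There the immediate early list turned lower (0.1793), as did the sex-linked list (0.7951), and Wnt9b turned to +0.1059. Without the 2 arrays with the brightest hybridisation controls endothelium was at 0.1552, erythroid at 0.02486, and the immediate early list turned lower (0.7928) and Lhx1 to -0.3549.

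Over the fits that leave out each array in turn, the adjusted p ran from 0.002932 to 0.9719 for ureteric bud, 0.0027 to 0.1625 for endothelium, 0.009828 to 0.6388 for erythroid, 0.008554 to 0.192 for neuron, 4.34e-05 to 0.1429 for cell cycle, 0.4997 to 0.8952 for p53 targets, 0.02388 to 0.3345 for hypoxia, 0.04236 to 0.9054 for immediate early genes, 0.009828 to 0.2713 for Notch and 0.4997 to 0.972 for sex-linked genes. Of these, the ureteric bud, p53, immediate early and sex-linked lists, none of them called, turned direction in at least 1 fit. Xist ran from -0.005986 without mutant replicate 2 to 0.2522 without mutant replicate 3, Lhx1 from -0.03553 to 0.7266 and Cd109 from -0.0216 to 0.4612. The progenitor list ran from 6.68e-17 to 1.413e-10.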

Other observations

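The 13 lists in this paragraph were written after the table of all genes had been opened, so their directions are not independent of it. The list of interstitial collagens and related fibril genes was higher in 12 of 13 members (median +0.23, adjusted p = 0.000139 over these lists, 0.156 with an estimated correlation). Its largest differences were those of the dim Col9a2 (+1.24), Col9a3 (+0.98), the cartilage collagen gene Col9a1 (+0.59, SE 0.10) and Col2a1 (+0.51). The bright Col1a1, Col1a2 and Col5a2 differed little, at +0.14, +0.05 and +0.07. Antigen presentation by MHC class II was lower in 5 of 6 members (median -0.42, adjusted p = 0.00474, 0.0659 with an estimated correlation), with the brightest H2-Ab1 probe set at -2.12 (SE 0.37). Its other probe sets were at -0.97 and -0.63, the mean of its probe sets at -1.24, and H2-Ab1 was at -1.29 within the high-18S arrays. Cholesterol synthesis was lower in 8 of 9 members by small amounts (median -0.19, adjusted p = 0.00222, 0.0659 with an estimated correlation). The other 10 lists were not called, namely Wnt ligands and receptors (adjusted p = 0.760), FGF ligands and receptors (0.773), claudins (0.954), smooth muscle (0.954), retinoic acid response (0.783), posterior Hox genes (0.760), genital ridge (0.954), trunk and limb mesenchyme (0.370), differentiated nephron (0.773) and axon guidance (0.479). Medians and test directions differed in sign for smooth muscle, at +0.06 with a test pointing lower.

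Tested one by one, 2 of 45037 probe sets were called, both lower in the mutant, while 2032 had an unadjusted p under 0.05 where 2251.85 would by chance. A probe set of Cdh4 had a log2 signal of 7.04 ± 0.15 (SD, n = 5) in wild type and 5.52 ± 0.24 in the mutant (adjusted p = 0.0368), a larger difference than the -0.73 of the brightest Cdh4 probe set. A dim probe set of Cd109 was at 5.40 and 2.90 (adjusted p = 0.0218), while the brightest Cd109 probe set differed by +0.25 (-0.02 without wild-type replicate 5), so the 2 probe sets of Cd109 disagree.

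Of the tests that follow, the splits for called genes and the window around Wnt9b were set before the data were examined, and the splits for lists, the balanced splits and the 4 tests of the lower lists were chosen after the list results were seen. Splits other than that by genotype still hold more mutant arrays on a side than on the other. Their counts are therefore not free of a genotype difference. Of 100 splits drawn from the 126 ways to part the arrays into 5 and 5, 30 called as many genes as the real one, which called 1, with 4 as the highest other count. So did 16 of the 60 splits balanced over the 18S sets, and chance is not excluded for the number of called genes. Another split, of mutant replicates 1, 2 and 3 with wild-type replicates 1 and 4 against the rest, had 2556 genes with an unadjusted p under 0.05 against 999 for the real one. That split set 5 low-18S arrays apart from a group with all 4 high-18S arrays, which points to a structure of the arrays that follows the 18S signal. Strain sequence around the targeted locus does not account for the called gene, since 0 of 639 tested genes within 20 Mb of Wnt9b were called and Btbd11 lies on chromosome 10 while Wnt9b lies on chromosome 11. With 1 called gene the planned comparison of rates near Wnt9b and elsewhere has no power, and 6.42% of those genes against 5.48% elsewhere had an unadjusted p under 0.05 (Fisher's exact p = 0.290).

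Lists called numbered 10 in the real split, and 2 of the 100 splits gave as many, the real one included, with 10 as the highest other count. Without the list and genes from earlier work 7 lists were called, and 4 of the 100 splits gave as many, with 9 as the highest other count. The real split is balanced over the 18S sets, and among all 60 splits balanced alike 3 reached the count of 10 and 6 the count of 7, so chance is not excluded for either. With an estimated correlation 4 lists were called with 1 as the highest other count, and with both changes 1 list, that of Wnt targets (adjusted p = 0.0398), with 0 as the highest other count, so that 1 split, the real one, reached each count. Chance is left open for these counts too, since the first includes the list from earlier work and the least share that 60 splits allow, multiplied by the 4 versions tried, is 0.0667.

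For the lower progenitor, induction, Wnt target and FGF feedback lists, the genotype is the biological difference that the design names, and no mechanism was tested. Without the 2 arrays with bright hybridisation controls all 5 lists (the list from earlier work included) stayed lower. Their camera adjusted p was at most 0.000348. The 18S sets each held as many mutant as wild-type arrays. The labels do not give their origin, but no pair of arrays with shared title wording was divided between the sets. Within each set all 5 lists were lower (camera adjusted p up to 0.00740). These p-values rest on the preset correlation of 0.01, and camera called up to 10 lists in other splits. The lists were chosen for being lower over these same arrays, so a kept direction was likely in advance and decides little. What argues against the bright controls and the 18S signal as the source is the design. The bright controls fell on an array of each group, and the 18S sets were balanced between the groups. A lower share of progenitor cells in the mutant pools stays open, because the range of shifts of 5 other cell type lists, 0.257, was no larger than with permuted labels (exact permutation p = 0.849). Ureteric bud tissue left on the wild-type mesenchymes could by itself raise a list there only through members that the bud expresses more strongly than the mesenchyme. Bud tissue was not measured alone, so which members those are is not known here. For such members the explanation, which also needs a lower bud score in the mutant, stays open. That score was higher in the mutant by 0.135 (SE 0.338), but its 95% interval of -0.64 to 0.91 includes the progenitor score's difference of -0.59. Mutant replicate 4 widens the interval, at 6.41 against 7.37 to 8.04 in the other mutant arrays. The bud score differed by +0.50 within the low-18S arrays and -0.42 within the high-18S arrays, where the progenitor score differed by -0.63 and -0.52. The 2 sets point opposite ways, so the bud score cannot decide.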
